A study of Homo sapiens with 8 samples.

How the data were processed

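Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in WI-38 cells, a line of human fetal lung fibroblasts. Per the labels, 50000 cells entered each library and reads were 150 bp, paired. There were 8 libraries in 4 groups of 2: a control miRNA, a precursor mimic of miR-340-5p (miR-340), a small interfering RNA against LBR (siLBR), and ionizing radiation of 10 Gy (IR). The oligonucleotides were used at 50 nM for 4 days, whereas irradiated cells were kept for 10 days, per the labels. The series text gives the days less clearly, so the times are stated here only as far as the labels go. Replicate numbers are those of the labels: 1 and 2 for control, 3 and 4 for miR-340, 2 and 3 for siLBR, 1 and 2 for IR. Nothing in the labels says that libraries of a group came from separate cultures.

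The authors deposited 1 peak list per library, so libraries were not pooled. Peaks were called with MACS2 version 2.2.7.1 in broad, paired-fragment mode without a control library and with all duplicates kept, at q limits of 0.05 and 0.1, per the file headers. The background of each peak came from its own library, over windows of up to 10000 bp, per the file headers. Alignment with Bowtie2 2.1.0 to hg38 is named in the submitters' processing notes. Filtering of reads before peak calling is not given in the sources used here, and neither is a shift of read ends for the transposase. Per the file headers, the unit of the pileup column is coverage, the number of fragments stacked over a peak. The p-value and q-value columns hold −log10 values, as the authors deposited them. The fold enrichment column is the ratio of pileup to local background, as the authors deposited it. Scores and folds per peak are therefore the authors' own and were used only to describe, rank or filter peaks within a list; ranks in lists of different lengths show no change between libraries.

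The depth of each library, as total fragments in the file headers, ran from 13717434 in IR replicate 1 to 19729365 in siLBR replicate 3. The lowest pileup of any peak on the chromosomes was 5 fragments in both IR lists, 7 in siLBR replicate 3 and 6 in the other lists, so the lists did not share 1 limit of detection. A peak list holds no value for a region where no peak was called; absence of a peak therefore means no call at that depth and background. Shares of peaks in single libraries carry 95% Wilson intervals in the underlying tables, and these cover counting error only.

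Peaks on chromosomes 1 to 22 and X were kept, and overlapping peaks within a library were merged. Gene positions came from a RefSeq gene table of GRCh38.p14, the same assembly as hg38 for the chromosomes, with 19970 protein-coding genes and without strand or sequence. The planned use of transcription start sites was therefore replaced by gene ends, and the planned motif, GC and exon or intron counts were left out. For each gene the promoter was taken as the window of 1 kb either side of 1 gene end: the end with a peak in more of the 8 libraries, chosen without regard to group. Among 42 genes of known strand, the end chosen was the 5′ end in 39, and CDKN1A, THY1 and MMP3 took the other end. In 1660 genes neither end held a peak. Among 23 list members that gained or lost a peak in some setting, picked for this check after their values were seen, 15 had the 5′ end, strand being taken from general knowledge. The other 8 were BBC3, ISG20, PECAM1, COL3A1, CSF3, CLDN4, TIE1 and PTPRC. Promoter share counts peaks over either end of any protein-coding gene, distal peaks lie over 50 kb from all gene ends, and gene-poor peaks lie in the third of 1-Mb bins with the fewest genes.

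All lists were merged into 540611 regions, joined at an overlap of 1 bp. A region was gained where both libraries of the treatment and neither control library held a peak, and lost in the reverse case; promoters were scored in the same way. No p-value per region can be had from presence and absence in 2 against 2 libraries. Each count was instead set beside the counts from the other ways of parting the same 4 libraries, and the higher of these is given. Values per library were compared across all 4 groups by an exact permutation test of the between-group sum of squares over the 105 ways to part 8 libraries into pairs. The smallest p this test can give is 0.00952. With 2 libraries against 2 the smallest two-sided p is 0.333, and over the 15 ways without IR it is 0.0667. These p-values measure only the spread between these libraries, which may be technical. Overlap of base positions between lists was measured by the Jaccard index, with a one-sided exact test over the same 105 ways.

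Overlaps of regions between treatments, which share both control libraries, were set beside the number from independent lists and beside 100 simulated draws of unchanged groups against the observed controls. Draws came from a model with 1 propensity per region and 1 rate per library. The steps were run on simulated lists of 20000 sites before use, with 200 changed sites per direction. Changed sites were set present in every library of the treatment and absent from every control, or the reverse. That is the definition of gained and lost. Recovery of 100% of the gained and 100% of the lost sites was therefore fixed in advance, and does not measure sensitivity in real lists. The partition test called 4.80% of draws of independent normal values without a group difference, which were not peak lists.

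A total of 18 gene lists was used: LBR with RNF130, the host gene of miR-340, nuclear lamina and envelope, heterochromatin, p53 targets and CDK inhibitors, the senescence-associated secretory phenotype (SASP), interferon response, proliferation, replication-dependent histones, anti-apoptotic genes, fibroblast identity and matrix, epithelial, endothelial, leukocyte, and neural and muscle markers, olfactory and taste receptors, keratin-associated proteins and defensins, KRAB zinc fingers, and housekeeping genes. The KRAB zinc finger list took all genes named ZNF with a number, most but not all of which have a KRAB domain. Gained and lost promoters of each list were compared with those of all other protein-coding genes that could have changed by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 128 tests. Regions within 50 kb of list genes were set beside 10000 random gene lists matched on the number of regions in reach. Genes are not independent replicates, and neighbours of 1 family share regions. A repeat with 1 gene per cluster, matched on regions that could change, was therefore added after the data had been seen, as was a Benjamini-Hochberg adjustment of these two-sided comparisons over 144 tests. Of the lists outside the central 95% of random lists, 9 of 144 were so in the repeat, where chance alone would give about 7, and 1 passed after adjustment. Fisher's tests were likewise repeated with 1 gene per cluster of list genes within 100 kb that could have changed, also after the data had been seen. Genes named in the text are the 10 with the highest mean within-list rank among promoters gained, and likewise lost, in each comparison, and the members of the lists. Other names are marked as chosen after their values were seen. Unless a named gene was among those checked for strand, the end scored may be its 3′ end.

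Alternatives were peaks with a −log10 q of at least 5, lists shortened to their 89528 strongest peaks (the length of the shortest list), presence defined by 50% of a region covered, bins of 500 bp, a window of 3 kb, and each library left out in turn. Groups, tests, lists, the rule for named genes and these alternatives were set before the data were examined. Peaks with a pileup of at least 7, regions merged without the IR lists, peaks at either gene end, separate single controls, peaks near list genes per library at equal list length, and the cluster repeat were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Contigs outside the chromosomes and chromosome Y were left out of every comparison.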

Results

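Accessible chromatin was profiled in 8 libraries of WI-38 fibroblasts, cells that divide a limited number of times in culture and then senesce. The design asks how chromatin differs in cells treated in ways linked to senescence: a miR-340 mimic, an siRNA against LBR, and irradiation, each against a control miRNA. LBR, the lamin B receptor, is a protein of the inner nuclear membrane that ties heterochromatin to the lamina. Both the mimic and the siRNA are meant to lower it. The peak lists rested on 16501305 and 15784923 fragments in control replicates 1 and 2, and on 17375256 and 17029892 in miR-340 replicates 3 and 4. They rested on 16732201 and 19729365 in siLBR replicates 2 and 3, and on 13717434 and 14559207 in IR replicates 1 and 2. IR libraries differed from control both in exposure and in time in culture, 10 against 4 days, and no transfection is named for them.

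LBR, on chromosome 1 from 225401502 to 225428821, carried a promoter peak in all 8 libraries. The fold enrichment of that peak over its own library's background was 5.35 and 5.52 in control and 4.55 and 5.65 with miR-340. It was 4.35 and 4.50 with siLBR and 3.42 and 4.81 after IR, where folds belong to separate lists and show no change. An accessible promoter does not measure LBR RNA or protein, so it is no check of the knockdown. RNF130, the gene whose intron holds the miR-340 hairpin, likewise had a promoter peak in 8 of 8 libraries. The hairpin itself, on chromosome 5 from 180015303 to 180015397, had a peak within 1 kb in IR replicate 1 alone, from 180014126 to 180014525. Housekeeping genes such as GAPDH had a promoter peak for 17 of 17 members in each library, and the proliferation list, with MKI67 and TOP2A, for 32 of 33 members in each.

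Both IR lists were longer than every other list, while their strong peaks, strong promoter peaks included, were fewer. They held 277580 ± 65788 peaks (SD, n = 2), against 123627 ± 40537 in control, 98823 ± 13145 with miR-340 and 103166 ± 2548 with siLBR. The exact permutation test over all partitions into pairs did not separate the groups by peak number (p = 0.114). Median fold enrichment of the peaks was 3.09 ± 0.0321 in IR, 3.61 ± 0.173 in control, 3.39 ± 0.109 with miR-340 and 3.46 ± 0.0532 with siLBR (exact p = 0.0476). Peaks with a −log10 q of at least 5 went the other way, with 15497 ± 2167 in IR and 41923.5 ± 6553 in control (exact p = 0.0286). Promoters with such a strong peak numbered 6007 ± 948 in IR, 12513 ± 404 in control, 11432.5 ± 299 with miR-340 and 10808.5 ± 477 with siLBR. That difference had the smallest p the exact test can give, 0.00952.

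Gene-poor bins, those with at most 2 protein-coding genes per Mb, held 24.5% ± 4.01 of IR peaks and 16.4% ± 1.39 of control peaks (SD, n = 2). Their share was 13.3% ± 0.375 with miR-340 and 14.3% ± 0.400 with siLBR, and both libraries of each lay below both controls. Windows placed evenly over the genome would put 34.8% there. Distal peaks, over 50 kb from any gene end, made up 43.1% ± 3.69 in IR, 33.7% ± 2.44 in control, 29.4% ± 1.04 with miR-340 and 31.0% ± 0.372 with siLBR. Both shares differed between groups at the smallest exact p, 0.00952. With all lists shortened to 89528 peaks the gene-poor shares were 20.7% ± 4.02, 15.3% ± 0.135, 13.1% ± 0.118 and 14.2% ± 0.0964 in the same order (exact p = 0.00952). Among peaks with a −log10 q of at least 5 the exact p was 0.143 for gene-poor and 0.581 for distal shares. There the IR shares, at 15.2% ± 3.76 and 26.8% ± 6.89, lay closer to control, at 12.7% ± 0.698 and 25.7% ± 1.54, while those with miR-340, at 10.5% ± 0.919 and 21.1% ± 2.23, lay below both controls in both libraries. Without miR-340 replicate 3 or siLBR replicate 2 the exact p of the gene-poor share was 0.0762 or 0.0571, and that of the distal share 0.0667 or 0.0762. Without miR-340 replicate 4 or siLBR replicate 3 the latter was 0.0667 or 0.0762 as well. Each treatment against control alone could reach no p below 0.333 in a two-sided exact test.

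**Figure D1:**
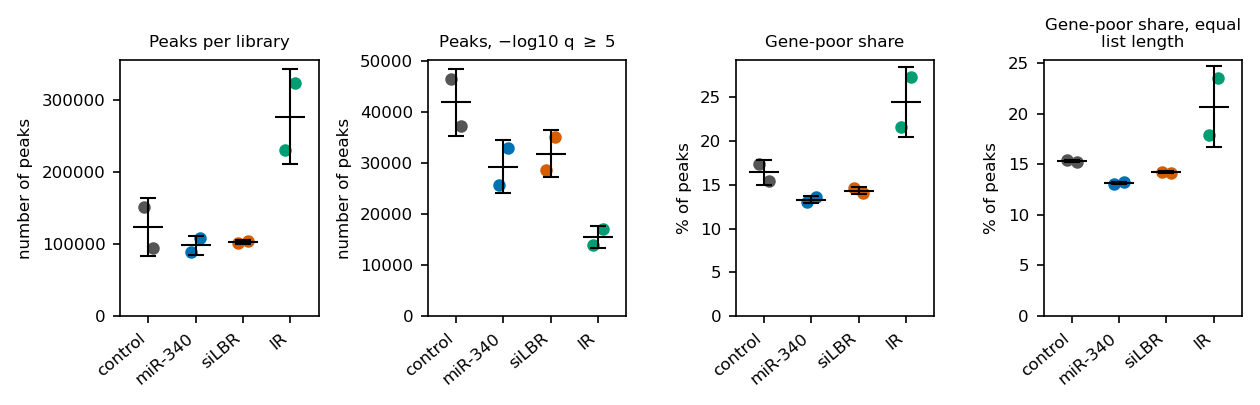
Number of peaks per library, number of peaks with a −log10 q of at least 5, and the share of peaks in gene-poor bins in percent, as deposited and at equal list length; points are libraries, and bars show mean ± SD of 2 libraries per group. IR lists hold 277580 peaks on average but only 15497 strong ones, and their gene-poor share stays above the other groups at equal length, at 20.7%.

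On average, libraries of a group shared more of their open bases than libraries of different groups, but single pairs departed from this. The mean Jaccard index was 0.313 within groups and 0.231 between them, the highest of all partitions, and the highest other partition gave 0.294 (one-sided exact p = 0.00952, the smallest possible). The siLBR pair shared most, 0.411, and the IR pair least, 0.137. IR replicate 1 shared 0.154 to 0.176 with each of the 6 libraries of other groups, more than with the other IR library. Control replicate 2 shared 0.327 to 0.391 with the miR-340 and siLBR libraries, above the 0.324 of the control pair. Leaving out 1 miR-340 or siLBR library ended the call, with exact p of 0.0857 and 0.105 without miR-340 replicates 3 and 4, and 0.0762 and 0.0667 without siLBR replicates 2 and 3. Without IR the index was 0.371 within groups and 0.322 between them, again the highest of 15 partitions.

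With miR-340, promoters of markers of other cell types were among those that gained a peak, and CXCL5 of the SASP and OAS2 of the interferon list lost theirs. CDH1, the epithelial cadherin on chromosome 16 at 68737292, had no peak in either control and fold enrichments of 3.08 and 3.19 with miR-340. CDH5, the endothelial cadherin at 66366691 on the same chromosome, had 3.13 and 2.73 against none in control. Both gains held at equal list length, but within 3 kb only that of CDH5 did. Both genes had a peak in every miR-340, siLBR and IR library. Their gains under each treatment therefore rest on absence from the same 2 control libraries. RGPD1, of the RanBP2-like family, gained a peak on chromosome 2 from 86913627 to 86913889 with folds of 7.78 and 7.01, but reads of its near-identical copies cannot be told apart. COX8C, a subunit of cytochrome c oxidase, gained one on chromosome 14 from 93346904 to 93347613 with folds of 5.22 and 5.67, and RAMACL one on chromosome 6 with 4.83 and 5.39. Among losses, CXCL5, a neutrophil-attracting chemokine of the SASP list, had folds of 5.65 and 4.25 in control and no peak with miR-340. OAS2, an interferon-induced enzyme that senses double-stranded RNA, had 3.78 and 3.41 in control and none with miR-340.

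By list, miR-340 lost 1 of the 31 SASP promoters open in control and gained none of the 3 closed ones. It lost 2 of 26 interferon promoters, OAS2 and ISG20 (Fisher's exact test, adjusted p = 0.488). Epithelial markers gained 2 of 3 closed promoters, CDH1 and CLDN4, and endothelial markers 2 of 4, CDH5 and TIE1, with adjusted exact p of 0.154 and 0.238. PECAM1, also endothelial, lost the peak at its 3′ end. Of the p53 list, BBC3, which encodes the pro-apoptotic protein PUMA, gained a peak at its gene end. For BBC3, CLDN4, TIE1 and ISG20 the end scored is the 3′ end, and none of the 4 gained or lost a peak at the 5′ end. Olfactory and taste receptor genes gained fewer peaks than other genes, 2 of 363 against 304 of 3766 (exact, adjusted p = 1.08e-08). They also lost more, 6 of the 16 that were open in control, OR4E1, OR4S1 and OR7E24 among them (exact, adjusted p = 9.33e-06). With 1 gene per cluster the losses passed but the gains did not (exact, adjusted p = 0.307). Tests of receptor losses, here and with siLBR and IR, did not match on peak strength. In control 10 of 47 and 7 of 21 open receptor promoters had a strong peak, against a mean of 12513 of 15022.5 promoters of all genes. The excess of losses therefore cannot be told apart from weak calls dropping out. Within 50 kb of receptor genes 27 regions were gained, against a median of 94 in random lists, and 10 against 37 with 1 gene per cluster (permutation over random lists, adjusted p = 0.00320 and 0.0288, the smallest possible before adjustment). Random lists were matched on regions of all 8 lists, IR included. Near receptor genes lay 976 and 1653 peaks in IR and 286 and 344 with miR-340, so the match may expect too many gains.

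Across the genome miR-340 gained 7191 regions and lost 12370, and the other splits of the same 4 libraries reached at most 7054 in total. The gained share of 36.8% was 49.8% at equal list length and 16.9% among peaks with a −log10 q of at least 5. Gene-poor bins held 13.04% of gained and 20.0% of lost regions, and 9.19% of gained and 4.66% of lost regions lay at gene ends. On chromosomes 19 and 22, both dense in genes, 64.9% and 60.3% of changed regions were gained, against 29.1% to 48.1% on the others. Promoters with a gained peak numbered 306 and those with a lost peak 268, with at most 201 in total for another split. Equal list length gave 448 and 201 instead, and strong peaks alone 152 and 675. The top-ranked losses included OVOL3, CERCAM, ZBTB46 and HNRNPL, the last a splicing factor, followed by AGXT2, GOLGA6C, CFAP73, SPMIP6 and OR7E24. The control peak at OVOL3, from 36114593 to 36116040, only met the edge of the 1-kb window around the gene end at 36113711. Besides RGPD1, COX8C and RAMACL the gains were CEL, AKR1E2, ARHGEF40, PLEKHG6, ANKRD62, HTR2A and KCNAB3. The gene table gives no strand, so the end scored may be the 3′ end. It was the upper end for CEL and ARHGEF40 and the lower end for HTR2A. Within 3 kb only RGPD1, RAMACL, COX8C, CFAP73 and OR7E24 kept a full difference. Without control replicate 2 the regions lost numbered 73038, and without control replicate 1 25347, while 13201 and 10063 were gained without control replicates 1 and 2. Without miR-340 replicates 3 and 4 regions gained were 30758 and 21421, and regions lost 16481 and 21164.

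**Figure D2:**
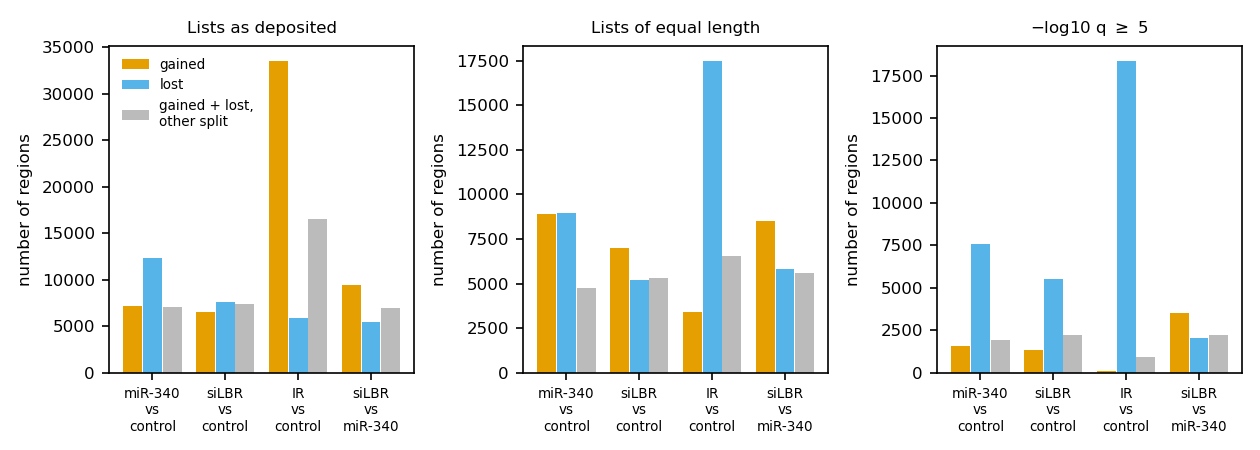
Regions gained, regions lost and the total for the higher of the other splits of the same libraries, as numbers of regions, for 4 comparisons in 3 settings: lists as deposited, lists of equal length, and peaks with a −log10 q of at least 5. For IR the larger bar is gained regions as deposited, 33496, and lost regions in the other panels, 17469 and 18349.

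With siLBR, a pair of interferon-induced chemokine genes that lie side by side on chromosome 4 gained promoter peaks. CXCL10, which draws activated T cells, spans 76021118 to 76023497 and had a peak from 76023454 to 76023844 in both siLBR libraries and in none of the other 6. Its fold enrichments were 4.94 and 5.59, and the peak lay above 82.2% and 86.3% of its list. CXCL11, from 76033682 to 76036070, had folds of 2.81 and 3.78 with siLBR and no peak in control, but it also had a peak in IR replicate 2. MMP12, a matrix-degrading elastase of the SASP list, had 3.12 and 3.45 with siLBR, none in control, and 2.60 in IR replicate 2. KRT28, a keratin of the hair root, gained a peak on chromosome 17 with folds of 4.29 and 5.05, and WFDC10A, of a protease inhibitor family, one on chromosome 20 with 4.06 and 8.16. H2BC18 and H3C13, histone genes that share 1 peak on chromosome 1, had a fold of 3.84 and 6.48 in control and no peak with siLBR; their copies are near-identical.

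The interferon list gained 2 of 3 closed promoters with siLBR, which did not pass after adjustment (Fisher's exact test, adjusted p = 0.0842), and the SASP list 1 of 3. CXCL10 kept its gain at equal list length, among strong peaks and within 3 kb, but with either gene end scored 1 control library had a peak too; MMP12 kept its gain at equal list length and within 3 kb, and CXCL11 within 3 kb but not at equal list length. Markers of other cell types changed beside them: CDH1 with folds of 2.82 and 3.01, CDH5 with 2.92 and 2.51, and the leukocyte gene PTPRC gained a peak, the last at its 3′ end. Of these, PTPRC and CDH1 but not CDH5 also gained a peak at equal list length. NPPA, the atrial natriuretic peptide gene, lost its peak as deposited but not at equal list length, with folds of 2.88 and 3.00 in control. BBC3 gained a peak here at both ends, and PECAM1, another endothelial gene, lost 1 at its 3′ end. Receptor genes of smell and taste gained 1 of 363 closed promoters, against 215 of 3766 other genes (exact, adjusted p = 1.98e-06), and lost 3 of 16 (exact, adjusted p = 0.0450). The latter did not pass at equal list length (exact, adjusted p = 0.225), nor without IR replicate 1 (0.0507). Neither passed among strong peaks, or with 1 gene per cluster (exact, adjusted p = 0.703 for gains and 0.111 for losses). Within 50 kb of nuclear lamina and envelope genes 19 regions were gained, against a median of 11 in random lists, and 18 were lost, against 12, neither past the test (permutation over random lists, adjusted p = 0.292 and 0.512).

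siLBR gained 6573 regions and lost 7626, and the other splits reached up to 7369, so the total of 14199 was 1.93 times as large. The gained share of 46.3% was 57.2% at equal list length, 56.3% among peaks with a pileup of at least 7, and 19.5% among strong peaks. Regions gained lay in gene-poor bins in 15.4% and regions lost in 19.3%. On chromosomes 19 and 22, 61.2% and 60.1% of changed regions were gained, and 38.8% to 52.2% elsewhere. Promoters gained were 216 and lost 270, against at most 226 in another split. At equal list length they were 288 and 233, and among strong peaks 48 and 893. As with miR-340, the losses among strong peaks cannot be told apart from the lower share of fragment bases in the strongest peaks. Top-ranked gains also held RSPH6A, PLEKHG6, SLC25A30, DLK1, ANKRD62, SSBP4 and NFKBID. Top-ranked losses were OVOL3, at the window edge as above, CRIP1, RAB37, CERCAM, CGB7, HNRNPL, WASHC1, GOLGA6C, OR7E24 and ZNF540. Within 3 kb the full difference stayed for CXCL10, WFDC10A, KRT28, OR7E24 and ZNF540. Without control replicate 2, 67303 regions were lost and 10353 gained, and without control replicate 1, 19205 and 12814. Leaving out siLBR replicates 2 and 3 gave 22343 and 23136 gained, and 11963 and 14088 lost.

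After irradiation, MMP10, a matrix metalloproteinase of the SASP list, had no promoter peak, whereas all 6 other libraries did, with folds of 5.98 and 4.99 in control. EMCN, a sialoprotein of endothelium, had folds of 3.90 and 3.29 in IR and no peak in the other groups, and CD3D, a chain of the T cell receptor complex, had 2.72 in each IR library and likewise none in the others. CDH1, with 2.89 and 5.09, and CDH5, with 2.56 and 3.24, gained peaks here too. None of EMCN, CD3D, CDH1 and CDH5 was gained at equal list length, whereas the loss at MMP10 held there. GP1BB, a platelet glycoprotein on chromosome 22, gained one with folds of 2.92 and 4.08, and SLC22A12, the renal urate transporter on chromosome 11, with 4.38 and 4.53. Losses at high rank included ZNF443 and ZNF658, zinc finger genes with control folds of 6.89 and 7.09 for the former and 8.26 and 7.48 for the latter. FOXO3B, on chromosome 17, lost one with control folds of 8.19 and 7.49. ZNF658 and FOXO3B have near-identical copies, and H2BC18 and H3C13 again lost their common peak.

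The SASP list lost 1 of 31 promoters with IR as deposited, and endothelial markers gained 3 of 4, EMCN, CDH5 and TIE1 (Fisher's exact test, adjusted p = 0.958 and 0.173). For TIE1 the end scored is the 3′ end. At its 5′ end control replicate 2 held a peak and IR replicate 2 did not, so none was gained there. With lists of equal length 5 of 30 SASP promoters were lost, CXCL8, IL1B, MMP1, MMP10 and STC1, against 955 of 13701 others (exact, adjusted p = 0.388). Losses there took 10 of 60 histone genes, against 950 of 13671 (exact, adjusted p = 0.0953), and 2 of 23 p53 targets, about the share of other genes. Among strong peaks 34 of 52 histone promoters were lost, against 3996 of 11867 others (exact, adjusted p = 6.33e-04), but these 52 form 5 clusters, and with 1 gene in each the list did not pass (exact, adjusted p = 0.589). Olfactory and taste receptors gained 23 of 363, against 705 of 3766 others (exact, adjusted p = 1.01e-08), and lost 4 of 16 (exact, adjusted p = 5.69e-04). Keratin-associated proteins and defensins gained 5 of 121, against 723 of 4008 (exact, adjusted p = 2.35e-04). With 1 gene per cluster the receptor losses passed, but neither the receptor gains (exact, adjusted p = 0.703) nor the keratin-associated list did. None of these 3 calls held among strong peaks, the last did not hold at equal list length or within 3 kb, and without IR replicate 1 the receptor gains did not pass (exact, adjusted p = 0.173).

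IR gained 33496 regions and lost 5890, with at most 16493 in total for another split, and the direction turned with the setting. The gained share was 85.0% as deposited, 52.1% among peaks with a pileup of at least 7, 16.3% at equal list length and 0.585% among strong peaks. Gained regions lay in gene-poor bins in 22.1%, between the 12.5% of regions shared by all 4 libraries and the 34.8% of even placement. The promoter counts turned in the same way, from 728 gained and 162 lost to 144 and 960 at equal list length and 10 and 4030 among strong peaks. Here too, losses among strong peaks cannot be told apart from the lower share of fragment bases in the strongest peaks. Further top-ranked gains were ZNF768, HHAT, A2ML1, GCKR, TCP11L2, GFRA4, MORC1 and GEMIN4. Further losses were CNPY3, TMEM177, SEMA4C, DCDC2B, SPMIP6, PRDM13 and HAPLN1. Within 3 kb GP1BB, SLC22A12, ZNF658, FOXO3B, DCDC2B and ZNF443 kept the full difference. Without IR replicate 1 the regions gained were 226225 and without IR replicate 2 138845, with 14438 and 14779 lost. Without control replicate 2, 46301 regions were lost and 38248 gained, and without control replicate 1, 13858 and 45981.

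**Figure D3:**
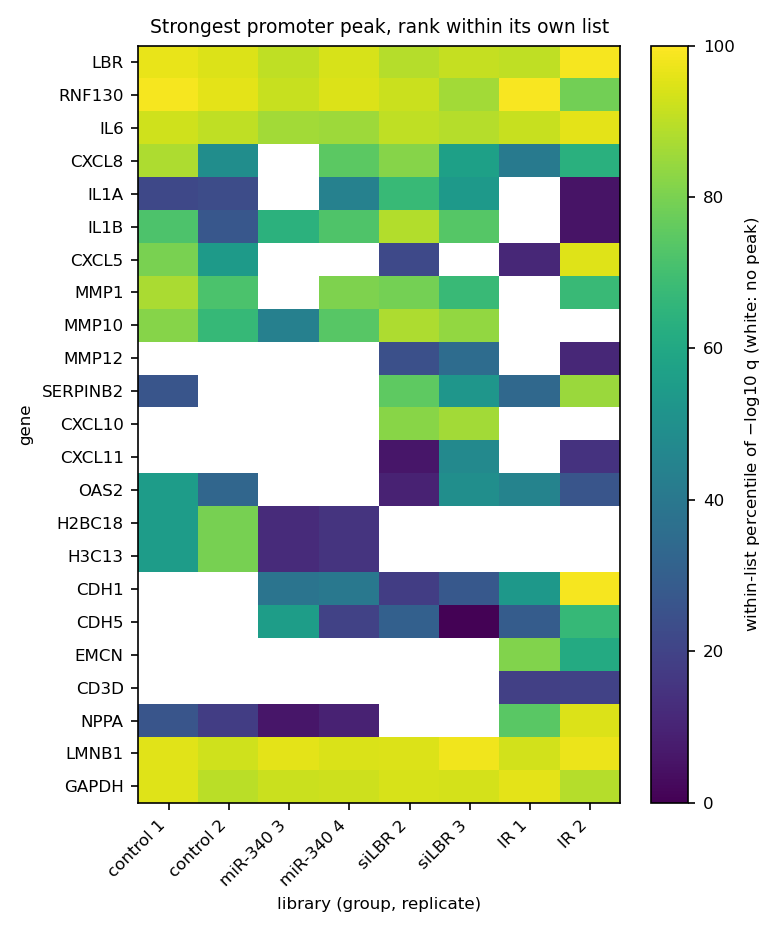
Strongest promoter peak of 23 genes in each of 8 libraries, coloured by its percentile of −log10 q within its own list, with white for no peak; colours of different libraries are not on 1 scale. CXCL10 has a peak in both siLBR libraries alone, at percentiles of 82.2 and 86.3, and LBR has one in every library.

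Set directly against miR-340, siLBR held promoter peaks at 3 of 6 interferon genes closed with miR-340, CXCL10, CXCL11 and OAS2, against 129 of 4370 other genes (Fisher's exact test, adjusted p = 0.00906). OAS2 had folds of 2.87 and 3.67 with siLBR, and 3.78 and 3.41 in control, so this difference was a loss with miR-340. At equal list length only CXCL10 of the 3 remained and the list no longer passed. Without miR-340 replicate 4 or siLBR replicate 2 its adjusted exact p was 0.0781 or 0.0944, and within 3 kb it was 0.0753. With 1 gene per cluster, which leaves 1 of the neighbours CXCL10 and CXCL11 at most, it was 0.703. SASP genes gained 2 of 4, MMP12 and SERPINB2 (exact, adjusted p = 0.0666), and 3 of 6 at equal length with CSF3 (exact, adjusted p = 0.00465), the last at its 3′ end. At the 5′ end of CSF3 both miR-340 libraries and neither siLBR library held a peak, the reverse of that gain. SERPINB2, an inhibitor of plasminogen activators, had folds of 4.02 and 3.15 with siLBR, none with miR-340, and 3.00 in control replicate 1. Within 50 kb of SASP genes 37 regions were gained, against a median of 17 (permutation over random lists, adjusted p = 0.00320), but 22 against 12 with 1 gene per cluster did not pass (adjusted p = 0.567). Per library at equal list length, peaks near SASP genes numbered 271.5 ± 2.12 with siLBR, 257 ± 2.83 with miR-340, 261 ± 12.7 in control and 205 ± 5.66 in IR (SD, n = 2). These did not differ past the exact test (p = 0.0667, adjusted 0.150).

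siLBR gained 9474 and lost 5454 regions relative to miR-340, with at most 6970 in another split. Gene-poor bins held 19.6% of the gained and 15.5% of the lost regions. Promoters gained were 132 and lost 194, 326 in total against 195 for another split, and strong peaks alone gave 108 and 325. Gains at the top included ZBTB46, AGXT2, CXCL10, SGK2, CES4A, ADCY7, KRT28, TRPV3 and MSMB. Of the 10 at the top, 8 also had a peak in both controls. Losses were RAB37, THRAP3, HSD11B2, TMEM101, RIIAD1, C1QTNF7, GPR89B, ZNF519, ADTRP and APOBEC3D. Within 3 kb CXCL10, KRT28, TMEM101, GPR89B, ZNF519 and APOBEC3D kept the full difference. Receptor genes gained 2 of 398, OR4E1 and OR4E2, against 130 of 3978 (exact, adjusted p = 0.00906), which did not pass at equal list length (exact, adjusted p = 0.0953), among strong peaks or with 1 gene per cluster (exact, adjusted p = 0.800). Leaving out siLBR replicates 2 and 3 gave 27028 and 27029 gained, and 8997 and 10500 lost. Leaving out miR-340 replicates 3 and 4 gave 13503 and 17385 gained, and 29611 and 19375 lost.

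**Figure D4:**
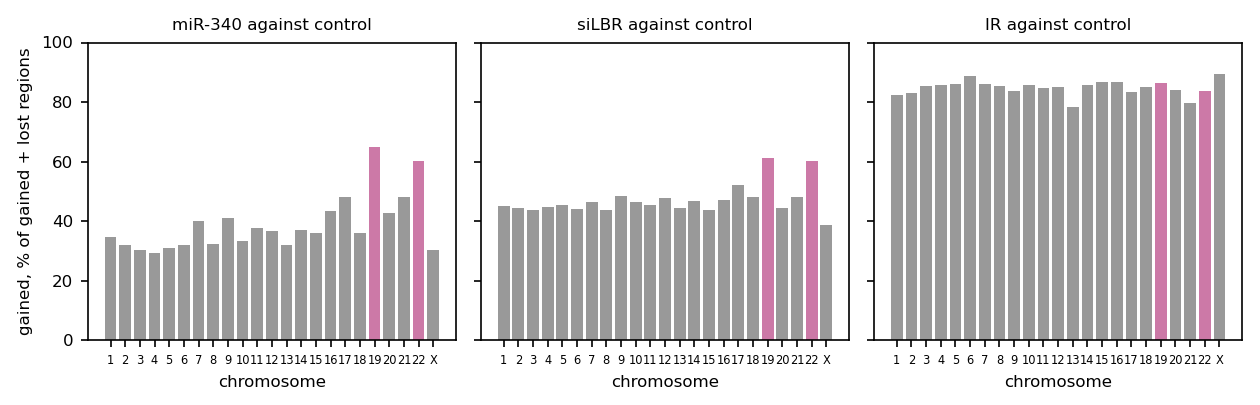
Share of changed regions that were gained, in percent of gained plus lost, on chromosomes 1 to 22 and X for each treatment against control, with 19 and 22 in colour. Both stand highest with miR-340, 64.9% and 60.3%, and with siLBR, 61.2% and 60.1%, but not with IR, 86.2% and 83.6%.

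Regions gained in both miR-340 and siLBR numbered 2093, or 29.1% of the former and 31.8% of the latter. Independent lists would share 127, and unchanged groups against the same controls 175 on average over simulated draws, 147 to 213. The 127 is low by construction, since its pool of 371884 regions without a control peak includes those called in IR alone. Regions merged without the IR lists numbered only 250401, with or without a control peak. The simulated number may be low too. Regions in 4 of the 6 libraries without IR and absent from a pair from different groups numbered at least 351. Regions lost in both numbered 4708, more than the 1286 of independent lists but fewer than the 5027 simulated. At equal list length the losses in common were 2957, above the simulated 1843, so that direction turned, and the gains 2553, above 606. Promoters gained in both were 135 and those lost in both 125, with no simulated number to set beside them. Chosen after their values were seen, the gains include CDH1 and CDH5 and the regulators GATA2, FOXA2 and POU5F1. The losses include GATA3, SHH, PAX9 and TAL1, and HPGD, which degrades prostaglandins. With IR, miR-340 shared 2512 gained regions, against 648 for independent lists and 1114 simulated, and siLBR 2179, against 592 and 1270. At equal list length these numbers were 639, with 628 simulated, and 494, below the 627 simulated. Lost regions in common with IR were 2662 for miR-340, against 993 and 713, and 2019 for siLBR, against 612 and 689. The control libraries are too few to be parted into sets of 2, and the excess over independent lists may come from the shared controls in part or in full. Simulated draws reached the number seen for losses with miR-340 and siLBR as deposited and for gains in common with IR at equal list length.

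Nuclear lamina and envelope genes had 16 or 17 of 17 promoters open in each library, heterochromatin genes 25 or 26 of 26, and anti-apoptotic genes 13 or 14 of 14. Between 23 and 24 of 25 p53 targets and CDK inhibitors were open per library, and 59 to 63 of 68 histone genes. LMNB1, encoding lamin B1, and IL6 had a promoter peak in every library. CDKN2A had a peak at the gene end scored in every library, which does not show that the start of its p16 transcript was open. Fibroblast and matrix genes were open at 25 to 28 of 29, and COL3A1 alone gained a peak, with IR and at its 3′ end. Leukocyte markers were open at 7 to 10 of 15, neural and muscle markers at 8 to 14 of 15, epithelial markers at 9 to 14 of 16 and endothelial markers at 6 to 11 of 12. KRAB zinc finger genes were open at 408 to 426 of 477; they lost 9 of 409 with IR, 4 with siLBR and 3 with miR-340, none past the test. Receptor genes were open at 79 and 157 of 415 in IR, 47 and 21 in control, 14 and 12 with miR-340, and 22 and 17 with siLBR (exact p = 0.0286). Strong peaks turned this order for IR, with 2 and 5 against 10 and 7 in control (exact p = 0.152), and lists of equal length gave 30 and 40 against 29 and 19 (exact p = 0.0190). Keratin-associated proteins and defensins were open at 30 and 32 of 133 in IR and at 7 to 11 elsewhere (exact p = 0.0857).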

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

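The tests of the IR lists, of the gene-poor shares and of lower LBR below were chosen after the result was seen; those of shared controls and of list length for the regions gained in common were set before the counts of the other pairs of libraries were seen, except that pairs from 1 group and from different groups were set apart afterwards.

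Relative to control, miR-340 and siLBR moved one way and IR the other in 3 measures of the peak lists. The gene-poor share differed from control by −3.10 percentage points with miR-340, −2.10 with siLBR and 8.07 with IR. The distal share differed by −4.30, −2.69 and 9.38 points, and median peak width by −87, −104 and 80 bp. Every library of a treatment lay on the stated side of both controls. This depended on the setting: among peaks with a −log10 q of at least 5 the IR width differed by −33 bp and the IR distal share by 1.18 points, and the distal share of siLBR replicate 3 lay above that of control replicate 2. With lists of equal length the IR widths no longer both lay above the controls. The difference between the treatments' effects was not tested on its own.

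Contigs outside the chromosomes, which entered no comparison, held 0.129% of peaks with miR-340, 0.0870% with siLBR and 0.0853% with IR, each above the 0.0667% ± 0.00530 of control (SD, n = 2).

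Both IR lists were longer and weaker than the other lists. IR libraries had fewer fragments and were called down to a lower pileup; among peaks with a pileup of at least 7 the mean IR list was 1.45 times as long as that of control, but IR replicate 1, with 123385 peaks, lay below control replicate 1, with 124361. Fewer fragments sequenced therefore cannot be told apart from the other explanations with 2 libraries per group. An even spread of fragments over the genome would put 34.8% of gained regions in gene-poor bins, and 22.1% lay there, so strictly even placement was not the sole source. That placement counts all bases alike, also those where no read can be placed. It therefore cannot exclude uneven background as the source. Regions in all 4 libraries had 12.5%. Irradiation and the longer culture cannot be told apart from a difference in library quality: only 108 regions were gained among peaks with a −log10 q of at least 5, but few strong gains do not exclude a change in weak ones.

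miR-340 and siLBR gained 2093 regions in common. Regions in 4 of the 6 libraries without IR and absent from the other pair numbered 4068 for the miR-340 pair, 1038 for the siLBR pair and 351 to 1433 for pairs from different groups. The count for the controls thus lay above 13 of the 14 other pairs, but the higher pair was itself of 1 treatment. By this count 15 pairs are too few to exclude shared control libraries. Simulated unchanged groups against the same controls shared 147 to 213 regions, and 551 to 653 at equal list length. As deposited that range lay below the lowest count for pairs from different groups, 351. The model may thus understate absence from 2 libraries at once, and cannot decide whether random absence from the shared controls was the full source. At equal list length the range lay within the counts of such pairs, 333 to 968. A difference carried by both control libraries was not simulated and is not excluded. Length of the lists was not excluded either: at equal list length the miR-340 pair gave 3381, the controls 2553, the siLBR pair 903 and pairs from different groups at most 968. Lower LBR in both treatments stays possible as a hypothesis, and with 15 pairs of libraries it cannot be told apart from a difference carried by both controls.

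miR-340 and siLBR lists held fewer gene-poor peaks than the control lists. Length of the lists does not account for all of it, since at equal length the share was 13.1% with miR-340 and 15.3% in control, and the siLBR libraries lay below both controls too. The differences shrank, however, from −3.10 to −2.20 points with miR-340 and from −2.10 to −1.14 with siLBR, so a part from length stays open. A shift of fragments to DNA rich in G and C may contribute: at equal length the gene-dense chromosomes 19 and 22 held at least 5.65% of peaks in each miR-340 and siLBR library and at most 5.16% in control. Without a genome sequence, gene density and GC content could not be parted. Lower LBR, with 14.2% for siLBR at equal length, cannot be told apart from GC content or transfection by this design.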

How the results depend on the processing

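Peaks with a pileup of at least 7, regions merged without the IR lists, either gene end, separate single controls, peaks near list genes per library and the cluster repeats were tried after the data had been seen; the other alternatives were planned. Counts of regions moved with most settings, and the cause was not tested. Among peaks with a −log10 q of at least 5, regions gained and lost were 1546 and 7589 with miR-340, 1334 and 5502 with siLBR, 108 and 18349 with IR, and 3513 and 2064 for siLBR against miR-340. With 50% of a region covered, regions gained were 3775, 3265, 19954 and 4626 in that order, and regions lost in the last comparison 3254. Bins of 500 bp gave 23146 and 41330, 19359 and 28415, 106829 and 23212, and 25623 and 17052, being smaller units. At equal list length IR gained 3396 and lost 17469, and with a pileup of at least 7 it gained 10949 and lost 10078. The gained share turned to 57.2% and 56.3% for siLBR at equal list length and with that pileup, and to 0.585% and 16.3% for IR among strong peaks and at equal list length. Regions merged without the IR lists kept the counts of the comparisons that do not involve IR within 1.5 times.

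Leaving out 1 library asks for fewer libraries to hold or lack a peak, which raises counts. Gained and lost regions then ranged from 10063 to 30758 and 16481 to 73038 with miR-340, from 10353 to 23136 and 11963 to 67303 with siLBR, from 38248 to 226225 and 13858 to 46301 with IR, and from 13503 to 27029 and 8997 to 29611 for siLBR against miR-340. The highest losses against control came without control replicate 2, the shorter control list.

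For the group tests, exact p among strong peaks was 0.0286 for peak count, 0.0190 for covered length, 0.324 for width, 0.581 for the distal share, 0.143 for the gene-poor share and 0.552 for the promoter share. At equal list length it was 0.0190 for covered length and 0.00952, the smallest possible, for the promoter share, against 0.105 as deposited. With each library left out, exact p ran from 0.0190 to 0.0762 for width, 0.0190 to 0.248 for promoter share, and 0.00952 to 0.0762 for the distal and the gene-poor share. For sharing of bases within groups it ran from 0.00952 to 0.105.

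Gene lists past the threshold numbered 9 as deposited, 3 among strong peaks, 2 with 1 gene per cluster, which leaves fewer genes to test, and 7 to 16 with each library left out, with 14 without control replicate 1 and 16 without control replicate 2. Of the 9 calls as deposited, 7 were weaker among strong peaks and 4 at equal list length. Lists outside the central 95% of random lists for nearby regions fell from 25 to 9 of 144 with 1 gene per cluster, where chance alone would give about 7, and those past the threshold after adjustment from 16 to 1. Of the 80 named promoters 61 kept the full difference among strong peaks, 67 at either gene end, and 22 within 3 kb, where a peak between 1 and 3 kb from the gene end counts too.

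The ratio of shared to simulated regions moved among strong peaks and at equal list length, in that order. It was 3.90 and 4.22 for gains and 2.14 and 1.60 for losses in both miR-340 and siLBR, 0.989 and 0.787 for gains and 1.505 and 1.79 for losses in siLBR and IR. For miR-340 and IR it was 1.52 and 1.02 for gains and 1.72 and 2.76 for losses. Separate single control libraries give, by construction, the same 2093 gained and 4708 lost regions in common to miR-340 and siLBR, so these counts test nothing further. The ratio to independent lists moved, from 16.5 to 8.77 and 8.28 for gains and from 3.66 to 1.81 and 1.49 for losses.

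Control and IR share only the numbers 1 and 2. With a replicate block, regions that differed the same way in both pairs were by definition the same 33496 gained and 5890 lost; deviations of same-numbered libraries correlated at 0.0368 over 540611 regions, and the exact sign-flip test of peak number gave p = 0.5, the smallest that 2 pairs allow. Motif, GC and exon counts with their alternatives were not run, as no genome sequence was used here. Depth limits what absence of a peak means, since the lowest pileup called was 5 to 7 fragments.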

Other observations

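The counts of peaks near list genes at equal list length were chosen after the data had been seen, and no explanation is offered for them.

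At equal list length the IR mean lay below that of control near 14 of the 18 gene lists, housekeeping genes included, with 120 ± 4.24 against 135.5 ± 7.78 peaks (SD, n = 2). As deposited, where IR lists are longer, the order was the reverse, with 434.5 against 249 near nuclear lamina and envelope genes. At equal length and within 50 kb of the latter, such as LMNA and LMNB1, 152 ± 11.3 peaks lay in IR, 191 ± 1.41 in control, 206.5 ± 7.78 with miR-340 and 196 ± 4.24 with siLBR. Histone genes had 68.5 ± 3.54 in IR and 84 in each control, with 86 and 89.5 ± 2.12 for miR-340 and siLBR. Heterochromatin genes, such as CBX5 and EZH2, had 225 ± 12.7, 246.5 ± 9.19, 280.5 ± 3.54 and 260.5 ± 3.54 in IR, control, miR-340 and siLBR. Each of these 3 lists had an exact p of 0.00952, the smallest possible, and 0.0429 after adjustment over 18 lists, as did leukocyte markers, where IR, with 85 and 86, lay next to control replicate 2, with 87. The means near fibroblast and SASP genes also lay below control, 251 against 355.5 and 205 against 261, but these lists did not pass (exact p = 0.105 and 0.0667). Among peaks with a −log10 q of at least 5 none of the 4 lists passed after adjustment, with 0.0571 to 0.0908, and miR-340 lay below control, with 82.5 against 98.5 near lamina and 122.5 against 147 near heterochromatin genes. Near olfactory and taste receptors the order was reversed, with 399.5 ± 64.3 in IR and 330 ± 11.3 in control, which did not pass after adjustment (exact p = 0.0286, adjusted 0.0857).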
